A study of Mus musculus with 11 samples.

How the data were processed

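RNA was sequenced from lymph node CD4+ cells of WT mice and of mice with a conditional deletion of Pggt1b in macrophages (GLC). The authors deposited whole-number counts of reads per gene, 1 column for each of 11 libraries, over 55471 Ensembl genes. Per the submitters' processing notes, STAR and featureCounts were used with the mouse build mm10; versions, the gene annotation, the strand setting, the treatment of reads that map to several places and any trimming are not given in the sources used here. These deposited counts were not normalized. Total counts per library ranged from 11308285 to 14620148. Paralogs, pseudogenes and overlapping or antisense genes can share or lose reads under such counting, so values of immunoglobulin segments, guanylate binding proteins and pseudogenes are uncertain in that respect.

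Gene symbols, types and positions were taken from GENCODE M21 (GRCm38, the assembly that mm10 names), which matched 55230 of the 55471 identifiers; unmatched genes held 0.0029% of counts. Samples were grouped by their titles, and 0 columns were left without a sample. Pairs of libraries were compared over genes with at least 10 counts in every library; the chi-square per degree of freedom lay between 9.48 and 62.8, where sampling noise alone gives about 1, so no library was treated as a copy of another. Sex, cage, litter and processing day are not given in the sources used here, and no batch could be modelled from the labels.

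Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (12404 genes), library sizes were scaled with TMM, and WT and GLC were compared over 5 and 6 libraries with glmQLFit and glmQLFTest, two-sided, without covariates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A positive log2 fold change means higher in GLC. CPM values use the scaled library sizes, and log2 CPM values add a prior count of 2. Standard errors were derived from the quasi-likelihood F statistic. The common biological coefficient of variation was 0.16.

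A total of 36 gene lists were fixed before the data were examined, in 4 kinds: T cell states and the targeted pathway, signalling and metabolism, other cell types, and technical signs. The 31 lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. The results of 1 of these lists and of some list members are not reported here. Each list was also tested with an estimated correlation, with fry, and by an exact permutation test of the list mean per library over all 462 splits of the libraries. Of the lists, 12 passed with the preset correlation, 11 higher and 1 lower, and 0 passed with an estimated correlation, fry or the exact test. Exact permutation tests were two-sided and were also used for library measures. The rule for naming genes, fixed in advance, took Pggt1b and Lyz2, the 10 genes of largest fold change in each direction past the threshold, the 5 of smallest p in each direction as not passing where fewer passed, and up to 4 members of smallest p from each list, a part of which is printed; predicted genes, clones, pseudogenes and receptor segments were left out of it and counted by family.

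The edgeR step was tested on simulated data after the fit to the real data. Counts for 12404 genes were drawn, each gene independently, from the means and dispersions of that fit and the real library sizes. In each of 5 simulations of the comparison of GLC with WT, 200 genes were changed. Changes of 1.25-fold, 1.5-fold, 2-fold and 4-fold were found for 15.2%, 52%, 75.6% and 94.8% of changed genes, and 0.0524% of unchanged genes were called.

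Alternatives were RLE and upper quartile scaling, a robust fit, no filter beyond at least 1 count, a filter of at least 1 CPM in 5 libraries, immunoglobulin, haemoglobin and mitochondrial genes left out, the B cell or macrophage list mean as a covariate, 2 surrogate variables from sva 3.50.0, limma-voom with and without quality weights, DESeq2 1.42.0, a threshold of 0.1, and each library left out in turn. Added after seeing the data were the share of counts in Gm42418 as a covariate (for the regulatory list also without WT replicate 1), GLC replicates 9 and 78 left out together, the exact test of list means, and library measures with 1 library left out. Splits of the 11 libraries into 5 and 6 were refitted for 100 of the 462 possible splits, the real one included. Figures were drawn with matplotlib.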

Results

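Gene expression was measured by RNA sequencing in CD4+ cells from the inguinal and axillary lymph nodes of C57BL/6 mice. The cells had been isolated with an untouched selection kit, which removes other cells with beads, and cultured with concanavalin A, a lectin that activates T cells. The data hold 11 libraries. The WT group has 5 libraries, and the GLC group has 6 libraries from mice in which Pggt1b was deleted conditionally in macrophages with a Lys-Cre driver. Pggt1b encodes a subunit of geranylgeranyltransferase type I, an enzyme that attaches a lipid to other proteins. GLC replicate 78 was made from RNA pooled from 2 mice. Libraries held between 11308285 and 14620148 counts. The WT libraries were deeper (mean 13.9 M ± 0.675 M counts, SD, n = 5) than the GLC libraries (mean 12.1 M ± 0.652 M, SD, n = 6; two-sided exact permutation test, p = 0.00433, adjusted p = 0.0303 over 7 library measures). With 1 library left out the difference was between -1.57 and -2.03 M. The adjusted p of the exact test was then 0.0333 without WT replicate 4 and between 0.05 and 0.111 without any other library. Fewer libraries leave fewer splits, which limits how small this p can be. Without GLC replicate 12 an exact permutation p of 0.00794 had an adjusted p of 0.0556. Y-linked genes had 633 counts in GLC replicate 9 and at most 1 count in any other library, and Xist had 11 counts there and between 2992 and 5943 elsewhere. The comparison asks how the transcripts of lymph node CD4+ cells differ when macrophages lack Pggt1b.

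Pggt1b transcripts were present in CD4+ cells of both groups. Pggt1b (ENSMUSG00000024477, chromosome 18, positions 46235351 to 46280993, GRCm38) was at 39.3 ± 4.52 CPM (counts scaled to library size; SD, n = 5) in WT and at 49.1 ± 6.70 CPM (SD, n = 6) in GLC. Its log2 CPM in WT replicates 1 to 5 was 5.07, 5.20, 5.30, 5.49 and 5.42. In GLC replicates 6, 78, 9, 10, 11 and 12 it was 5.84, 5.69, 5.73, 5.64, 5.25 and 5.51. The log2 fold change was 0.32 (SE 0.10, 95% interval 0.10 to 0.54), and 5 of 6 GLC libraries lay above the WT mean, but the adjusted p was 0.9997 in edgeR's quasi-likelihood test. The deletion is described for macrophages only, so the level in CD4+ cells does not check the labels. Lyz2 (ENSMUSG00000069516, chromosome 10, positions 117277331 to 117282321), the lysozyme gene whose promoter gives the Lys-Cre driver its name, had 12 counts over the WT libraries, 9 of them in WT replicate 1. It had 0 counts in the GLC libraries, which allows a level of up to 0.0412 CPM over that group. Intervals and limits of this kind cover counting error only.

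No single gene separated the groups past the threshold. Of 12404 genes tested, 0 were higher and 0 were lower in GLC at an adjusted p of 0.05 with edgeR, and 563 had an unadjusted p under 0.05 (341 higher and 222 lower), against 620 expected by chance. That count was 320 without WT replicate 2, 366 without GLC replicate 78, 771 without WT replicate 5, 789 without GLC replicate 11 and 901 with voom and quality weights. The smallest adjusted p was 0.0665 without WT replicate 5. With all libraries the smallest adjusted p, 0.495, belonged to Igkv5-48, an immunoglobulin kappa variable gene on chromosome 6 (positions 69726573 to 69727138), which was at 0.184 ± 0.258 CPM in WT and 4.19 ± 3.71 CPM in GLC. DESeq2 called 2 genes higher and 0 lower, Igkv5-48 (adjusted p = 0.0143) and Ighv3-8 (adjusted p = 0.0248), both named here after their values were seen. Without a filter on low counts edgeR called Igkv5-48 alone (adjusted p = 0.00706), and limma-voom called 0 genes with 538 at an unadjusted p under 0.05. The median 95% interval of a fold change reached 0.251 to either side on the log2 scale, and 0.168 for the 5451 genes with a mean log2 CPM over 5.

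The genes of smallest p, none of which passed (adjusted p = 0.9997 in edgeR for each) lay on both sides. On the higher side, Ryr1, an intracellular calcium release channel, had a log2 fold change of 1.86 (SE 0.42), from 0.290 ± 0.130 CPM in WT to 1.08 ± 0.449 CPM in GLC. Ryk, a receptor for Wnt ligands, was at 1.34 (SE 0.33), and Gucy1a1, a subunit of soluble guanylate cyclase, at 1.59 (SE 0.41). Cyth4, an exchange factor for Arf GTPases, was at 0.35 (SE 0.09), and Incenp, a member of the chromosomal passenger complex, at 0.37 (SE 0.09). All 6 GLC libraries lay above the WT mean for each of these 5 genes. On the lower side the log2 fold changes were -0.33 for Hs3st3b1, a heparan sulfate sulfotransferase, -0.31 for Glo1, the glyoxalase that detoxifies methylglyoxal, -0.39 for Galnt10, an enzyme of O-glycosylation, -0.23 for Ccng2, a cyclin, and -0.29 for Ranbp10. None of the 6 GLC libraries lay above the WT mean for these 5 genes, whose SEs were 0.09, 0.08, 0.11, 0.06 and 0.08.

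**Figure D1:**
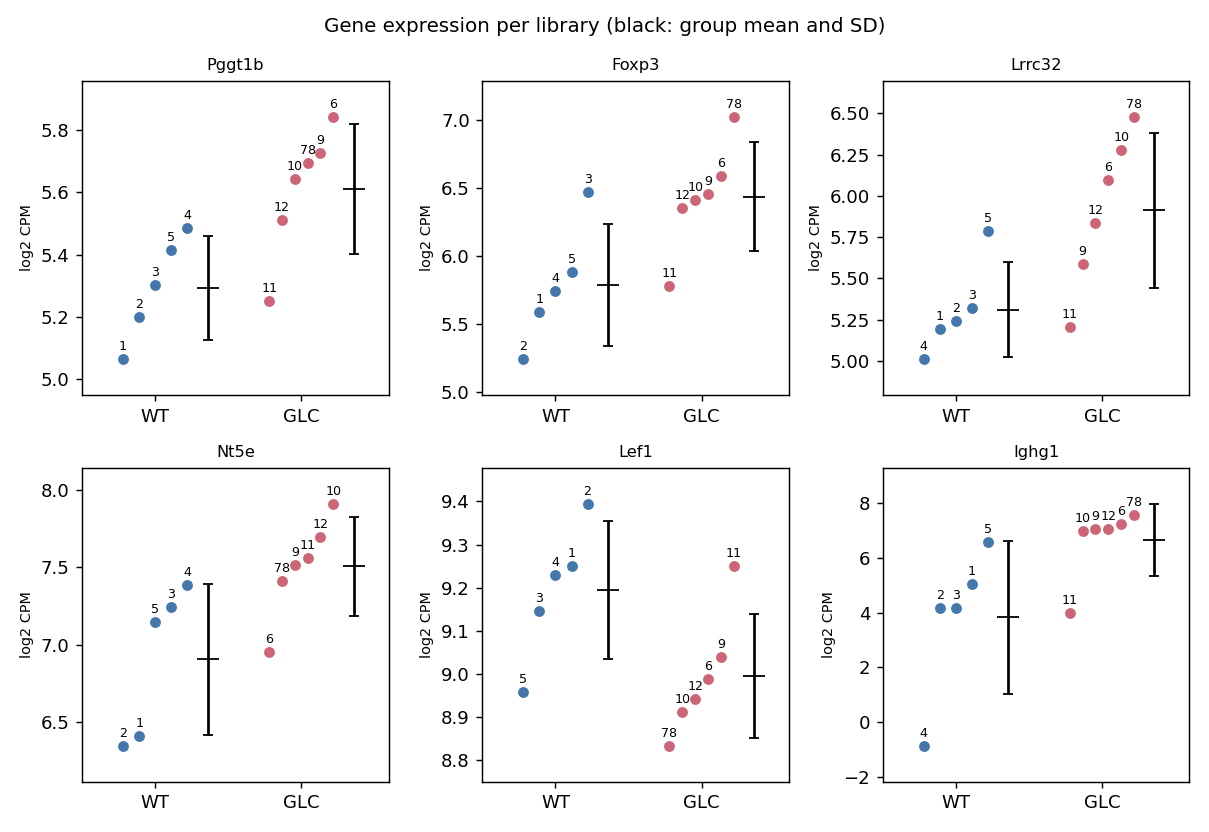
Log2 CPM of 6 genes in each library (points, numbered by replicate and spread sideways by value), with the group mean and SD in black, for 5 WT and 6 GLC libraries. Foxp3 is above the WT mean in 5 of 6 GLC libraries and Nt5e in 6 of 6, with overlap between the groups, and no gene shown passes the edgeR threshold.

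Of the gene lists of T cell states, all fixed before the data were examined, some passed a set test with a preset correlation and none passed with an estimated one. Regulatory T cell markers were higher in GLC: 27 of 28 measured members had a log2 fold change above 0, the median was 0.27, and the list passed a set test against all other genes (limma camera with a preset correlation of 0.01, adjusted p = 8.83e-07). With an estimated correlation the list did not pass (adjusted p = 0.504). Foxp3, the transcription factor that defines regulatory T cells, was at 57.3 ± 19.0 CPM in WT and 89.1 ± 24.3 CPM in GLC, a log2 fold change of 0.64 (SE 0.21). Lrrc32, which displays latent TGF-beta on these cells, had a log2 fold change of 0.64 (SE 0.20), Nrp1, a surface receptor on thymus-derived regulatory T cells, of 0.75 (SE 0.25), and Nt5e, the CD73 ectonucleotidase, of 0.57 (SE 0.20). No member passed over all genes, and 0 passed when adjusted over the list alone, where these 4 each had an adjusted p of 0.0824. The mean log2 CPM of the list was 4.89 ± 0.338 (SD, n = 5) in WT and 5.19 ± 0.353 (SD, n = 6) in GLC. This difference of 0.30 did not pass a two-sided exact permutation test (p = 0.182). It was 0.199 without WT replicate 2 and 0.19 without GLC replicate 78 (camera adjusted p of 0.00155 and 0.00124).

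Type 1 helper genes were higher in GLC in the same set test, with 15 of 16 members above 0 and a median log2 fold change of 0.41 (adjusted p = 2.28e-05; adjusted p = 0.504 with an estimated correlation). Their list mean lay above the WT mean in 6 of 6 GLC libraries. Il18rap, a subunit of the interleukin-18 receptor, was at 0.64 (SE 0.22), Hopx at 0.59 (SE 0.21) and Eomes, a T-box factor, at 0.67 (SE 0.27), while Fasl, a death ligand that the effector and memory list also holds, was at -0.30 (SE 0.12). Effector and memory genes were higher with 20 of 24 members above 0 and a median of 0.20 (adjusted p = 0.000899; adjusted p = 0.504 with an estimated correlation), led by Vim, an intermediate filament gene, at 0.39 (SE 0.13), Itgb1 at 0.42 (SE 0.16) and Nkg7, a cytotoxic granule gene, at 1.07 (SE 0.37). Without WT replicate 4 the effector and memory list no longer passed (adjusted p = 0.0938), and without GLC replicate 78 its mean difference went from 0.243 to 0.16 (adjusted p = 0.0435). Follicular helper genes were higher with 12 of 14 members above 0, including Tox2 at 0.73 (SE 0.30) and Pdcd1 at 0.59 (SE 0.27), and a list median of 0.16 (adjusted p = 0.0130; adjusted p = 0.553 with an estimated correlation). That list no longer passed without WT replicate 2, WT replicate 4, GLC replicate 78 or GLC replicate 9 (adjusted p of 0.097, 0.415, 0.0807 and 0.0513), and its mean difference of 0.229 was 0.129 without WT replicate 4. No member of these 3 lists passed over all genes or adjusted over the list alone.

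Genes of the naive state and of lymph node homing were lower in GLC, with 15 of 18 members below 0 and a median log2 fold change of -0.13 (camera adjusted p = 0.00021; adjusted p = 0.504 with an estimated correlation). Lef1, a transcription factor of naive T cells, had 589 ± 64.3 CPM in WT and 512 ± 53.2 CPM in GLC, a log2 fold change of -0.20 (SE 0.09). Il7r, the interleukin-7 receptor, was at -0.22 (SE 0.10), Klf3 at -0.18 (SE 0.09) and Ccr7, the chemokine receptor that guides T cells into lymph nodes, at -0.32 (SE 0.16). No member passed over all genes, and 0 passed when adjusted over the list alone (smallest adjusted p = 0.191). The list mean was 8.82 ± 0.0608 (SD, n = 5) in WT and 8.71 ± 0.1 (SD, n = 6) in GLC, with 1 of 6 GLC libraries above the WT mean (two-sided exact permutation test, p = 0.0606). B cell markers moved with these T cell lists. With the mean of the B cell list as a covariate the regulatory, effector and memory, follicular helper and naive lists no longer passed (adjusted p of 0.231, 0.659, 0.932 and 0.0537), and the type 1 helper list did (adjusted p = 0.0316) with its mean difference lowered from 0.381 (SE 0.193) to 0.213 (SE 0.176). The difference of the list mean went from 0.243 (SE 0.16) to 0.0496 (SE 0.0945) for effector and memory genes and from 0.229 (SE 0.162) to 0.0368 (SE 0.101) for follicular helper genes. For naive genes it shrank less, from -0.112 (SE 0.0514) to -0.0738 (SE 0.0511).

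**Figure D2:**
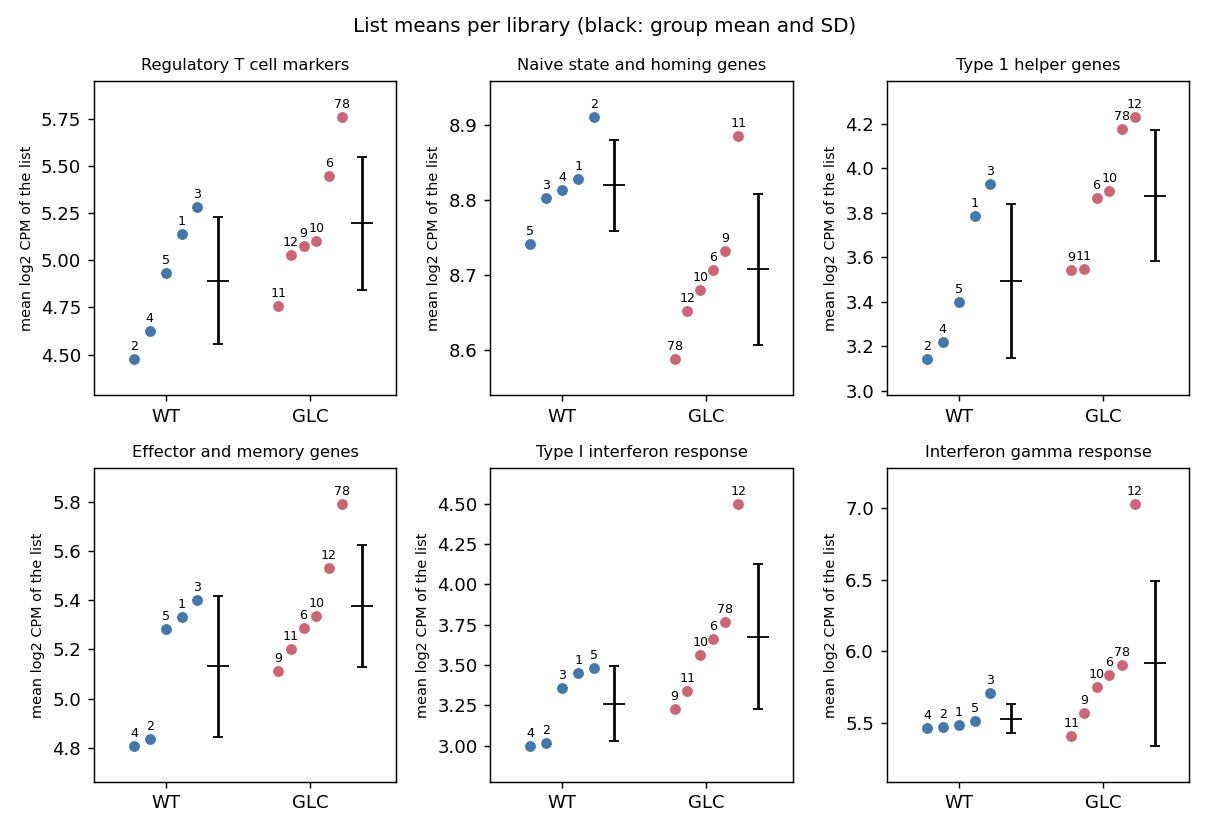
Mean log2 CPM of 6 gene lists in each library (points, numbered by replicate and spread sideways by value), with the group mean and SD in black, for 5 WT and 6 GLC libraries. The groups overlap in every panel, and GLC replicate 12 is highest in both interferon panels, at 4.50 and 7.03.

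Early activation genes, type 2 and type 17 helper genes, and prenylation and sterol genes did not pass the set test (camera adjusted p of 0.599, 0.216, 0.549 and 0.599). Among early activation genes, 20 of 30 members were below 0 and the median log2 fold change was -0.09, with Nfatc1 at 0.13 (SE 0.08) and Il2ra, the interleukin-2 receptor alpha chain, at 0.20 (SE 0.16). Type 2 helper genes included Il1rl1, the interleukin-33 receptor, at 19.4 ± 9.55 CPM in WT and 39.2 ± 20.8 CPM in GLC (log2 fold change 1.02, SE 0.37), and Ccr4 at 0.62 (SE 0.26). Type 17 helper genes included the cytokine Il17a at -1.03 (SE 0.46) and Ahr at 0.37 (SE 0.21), and this list's median (0.13) and mean (-0.000147) differed in sign. Among prenylation and sterol genes Ggps1, which makes geranylgeranyl diphosphate, was at -0.18 (SE 0.09). The list mean of the prenylation and sterol genes was 4.57 ± 0.0346 (SD, n = 5) in WT and 4.54 ± 0.0822 (SD, n = 6) in GLC. Calls of the early activation and type 2 lists, and the direction of the early activation list, depended on single libraries. Early activation genes passed as lower without WT replicate 4 or GLC replicate 6 (adjusted p of 0.0141 and 0.0149), and type 2 helper genes passed as higher without WT replicate 1 (adjusted p = 0.00994).

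Type I interferon response genes formed the list of smallest p in the set test with the preset correlation, but not with an estimated correlation, fry or the exact test. They were higher in GLC, with 27 of 28 members above 0 and a median log2 fold change of 0.42 (camera adjusted p = 6.12e-08; adjusted p = 0.504 with an estimated correlation). Interferon gamma response genes were higher with 21 of 21 members above 0 and a median of 0.45 (adjusted p = 8.83e-07; adjusted p = 0.504 with an estimated correlation). Xaf1 was at a log2 fold change of 0.64 (SE 0.23), Usp18, a deconjugating enzyme for ISG15, at 0.75 (SE 0.29), Mx1, an antiviral GTPase, at 1.32 (SE 0.55), Gbp2 and Gbp3, guanylate binding proteins, at 0.79 (SE 0.30) and 0.45 (SE 0.17), and Iigp1, an immunity-related GTPase, at 1.57 (SE 0.59). GLC replicate 12 carried much of this: Gbp2 was at 603.6 CPM there and between 147.2 and 207.3 CPM in the other GLC libraries. Without GLC replicate 12 the difference of the list mean fell from 0.415 to 0.251 for the type I list and from 0.387 to 0.164 for the interferon gamma list (camera adjusted p of 0.000135 and 0.00013). Without it the log2 fold changes were 0.39 for Xaf1, 0.43 for Usp18, 1.15 for Mx1, 0.31 for Gbp2, 0.27 for Gbp3 and 0.63 for Iigp1. With the B cell list as a covariate both interferon lists passed the preset test (camera adjusted p of 0.000406 and 0.000164). Their mean differences were then 0.267 (SE 0.231) for the type I list and 0.338 (SE 0.305) for the interferon gamma list. Without the covariate the SEs were 0.224 and 0.263.

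Cell cycle genes were also higher in GLC (24 of 28 members above 0, median log2 fold change 0.40, camera adjusted p = 0.000182; adjusted p = 0.504 with an estimated correlation), including Mcm6, a replicative helicase subunit, at 0.23 (SE 0.09), Rrm2, a ribonucleotide reductase subunit, at 0.74 (SE 0.32) and Birc5 at 0.91 (SE 0.39). The difference of the cell cycle list mean was 0.359, against 0.224 without GLC replicate 12 and 0.221 without WT replicate 2 (camera adjusted p of 0.0173 and 0.0125). Inhibitory receptor genes were higher (11 of 13 above 0, median 0.28, adjusted p = 0.0013; adjusted p = 0.504 with an estimated correlation), with Cd274, which encodes PD-L1, at 83.6 ± 15.4 CPM in WT and 118 ± 32.9 CPM in GLC and Tigit at a log2 fold change of 0.59 (SE 0.23). With the B cell list as a covariate the cell cycle and inhibitory receptor lists no longer passed (adjusted p of 0.231 and 0.245). Cytokine receptor and signalling genes did not pass (adjusted p = 0.549), with Jak3 at 0.56 (SE 0.18) and Ifngr2, a subunit of the interferon gamma receptor, at -0.40 (SE 0.13). Adhesion, chemokine receptor, NF-kB, glycolysis, oxidative phosphorylation, apoptosis and unfolded protein response genes did not pass either (adjusted p of 0.102, 0.503, 0.904, 0.156, 0.151, 0.549 and 0.222). Glycolysis genes did pass as higher without WT replicate 1 or GLC replicate 9 (adjusted p of 0.00994 and 0.0082), unfolded protein response genes as higher without WT replicate 1 (adjusted p = 0.00286), and oxidative phosphorylation genes as lower without WT replicate 3 (adjusted p = 0.00223). No member of these lists or of the interferon lists passed over all genes or adjusted over its list alone.

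Transcripts of antibody-producing and other cells were present at low levels in the selected cells. Plasma cell markers were higher in GLC, with 8 of 10 members above 0 and a median log2 fold change of 0.95 (camera adjusted p = 0.00126; adjusted p = 0.504 with an estimated correlation). Ighg1, the constant region of the IgG1 heavy chain, was at 32.8 ± 36.6 CPM in WT and 125 ± 58.0 CPM in GLC (log2 fold change 1.92, SE 0.70), and Ighg3 was at 1.59 (SE 0.67). B cell markers were higher with 8 of 11 members above 0 and a median of 0.44 (adjusted p = 0.00653; adjusted p = 0.553 with an estimated correlation), with Igkc at 169 ± 131 CPM in WT and 342.5 ± 172.5 CPM in GLC, and Cd74 and H2-Ab1, genes of antigen presentation by MHC class II, at 0.44 (SE 0.24) and 0.78 (SE 0.36). Natural killer markers were higher with 7 of 8 members above 0 and a median of 0.37 (adjusted p = 0.00503; adjusted p = 0.504 with an estimated correlation), including Tyrobp at 0.99 (SE 0.41) and Eomes, which the type 1 helper list also holds. Without WT replicate 4 the plasma cell, B cell and natural killer lists no longer passed (adjusted p of 0.0693, 0.229 and 0.0831), and the mean difference went from 1.13 to 0.632 for the plasma cell and from 0.461 to 0.23 for the B cell list (0.307 without GLC replicate 78). The B cell list also failed without WT replicate 2 (adjusted p = 0.09) and with no filter on low counts (adjusted p = 0.281), and the natural killer list without GLC replicate 6 or GLC replicate 78 (adjusted p of 0.07 and 0.0799). Cd79a, a member of the B cell list, had between 7 and 28 counts per library in WT and between 10 and 21 in GLC. This member thus gave no sign of more B cells in GLC. Without GLC replicates 9 and 78 together, a choice made after seeing the data, the B cell, plasma cell and follicular helper lists failed (adjusted p of 0.162, 0.0842 and 0.262).

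Of 88 immunoglobulin genes tested, 78 had a log2 fold change above 0 and the median was 1.04, under each of the 3 scalings tried, yet none passed with edgeR. Immunoglobulin genes took 0.0615% ± 0.0505 (SD, n = 5) of counts in WT and 0.130% ± 0.0650 (SD, n = 6) in GLC. This difference did not pass a two-sided exact permutation test (p = 0.0779, adjusted p = 0.136). Macrophage and monocyte, dendritic cell, CD8 T cell and gamma delta T cell markers did not pass the set test (camera adjusted p of 0.257, 0.126, 0.151 and 0.904). Dendritic cell markers did pass as higher without WT replicate 3, GLC replicate 9, GLC replicate 10 or GLC replicate 12 (adjusted p of 0.0378, 0.0436, 0.0255 and 0.0326). Lyz1, a second lysozyme gene, was at 0.570 ± 0.626 CPM in WT and 1.51 ± 1.02 CPM in GLC, and Fcgr3 had a log2 fold change of -0.51 (SE 0.29). Red cell and stroma lists had 1 and 2 measured members and neutrophil markers 0, so these lists were not tested with the filter on low counts. With no filter the stroma and neutrophil lists were tested and did not pass (camera adjusted p of 0.724 for each). The list means of the 7 tested lists of other cell types overlapped between the groups. For plasma cell markers the mean log2 CPM was 2.86 ± 1.28 (SD, n = 5) in WT and 3.99 ± 0.631 (SD, n = 6) in GLC (two-sided exact permutation test, p = 0.0736, the smallest among these lists).

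Genes near the targeted and driver loci were compared with the rest, since DNA flanking an engineered allele can come from another strain. Within 5 Mb of Pggt1b, 2 of 23 tested genes had an unadjusted edgeR p under 0.05, and within 5 Mb of Lyz2, 4 of 43 did (two-sided Fisher exact tests against all other tested genes, p = 0.281 and p = 0.13). Both numbers for the Pggt1b window, and its Fisher test, include Pggt1b itself (unadjusted edgeR p = 0.00743). None of these genes passed after adjustment. Heat shock and histone genes, tested as signs of handling and of RNA type, did not pass the set test (camera adjusted p of 0.956 and 0.904). The share of counts in Gm42418, a transcript overlapping a ribosomal RNA repeat, was 7.63% ± 1.42 (SD, n = 5) in WT and 6.50% ± 0.475 (SD, n = 6) in GLC (two-sided exact permutation test, p = 0.0455, adjusted p = 0.106). WT replicate 1 was at 10.0%, and without it the WT mean was 7.04% and the difference -0.537 (exact permutation p = 0.143). The share of Lars2, a mitochondrial leucyl-tRNA synthetase gene, was lower in GLC (0.411% ± 0.138, SD, n = 5, in WT and 0.290% ± 0.0383, SD, n = 6; two-sided exact permutation test, p = 0.013, adjusted p = 0.0455), with the highest WT value, 0.650%, in WT replicate 1. Without that library the difference went from -0.121 to -0.0619 (adjusted p = 0.15). With any other library left out it was between -0.116 and -0.144. The adjusted p of the exact test was then between 0.05 and 0.139, so no such run kept it under 0.05. Fewer libraries leave fewer splits, which limits how small this p can be. Without GLC replicate 11 an exact permutation p of 0.00794 had an adjusted p of 0.0556. In these runs the loss of the call thus does not by itself show dependence on a library. The shares of Gm42418 and Lars2 were both highest in WT replicate 1, and within GLC both were highest in replicate 11 and lowest in replicate 10. The lower Lars2 share was thus not shown to be separate from the Gm42418 share.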

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

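Chosen only after the result was seen were the comparison of GLC replicate 12 with other cell types, the Gm42418 covariate and the form of its test, the splits for the interferon list, the correlation within lists and the present form of the B cell tests. In the following values, 1 library of a group lay apart from the rest, with a gap over the group's range above Dixon's 95% critical value. Of 194 sets of values examined, 15 met this rule, against about 10 expected, since chance gives about 1 in 20.

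GLC replicate 12 was highest within GLC for the interferon gamma response list (7.03 against 5.41 to 5.91 in the other libraries, ratio 0.693), for Gbp2 (log2 CPM 9.24 against 7.20 to 7.70, ratio 0.757) and for Xaf1 (4.40 against 3.11 to 3.51, ratio 0.695). Among WT libraries, replicate 3 was highest for the interferon gamma response list (ratio 0.797), replicate 5 was highest for Xaf1 (ratio 0.817), and replicate 2 was lowest for Usp18 (ratio 0.731). GLC replicate 11 was lowest within GLC for Ighg1 (log2 CPM 4.00 against 6.98 to 7.56, ratio 0.838) and for Ryk (ratio 0.631). GLC replicate 78, the pool of 2 mice, was highest for the B cell list (3.92 against 2.83 to 3.14, ratio 0.715).

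WT replicate 1 was highest within WT for the share of mitochondrial counts (2.64%, Wilson 95% interval 2.64% to 2.65%, against 1.42% to 1.61%, ratio 0.842), for the share of Lars2 (0.65%, Wilson 95% interval 0.646% to 0.654%, ratio 0.729), for the histone list (ratio 0.771) and for Lyz2 (9 counts against at most 1, ratio 0.889). GLC replicate 11 was highest within GLC for Lars2 (0.365%, Wilson 95% interval 0.361% to 0.368%, ratio 0.704). GLC replicate 9 had 633 Y-linked counts, against at most 1 in the other GLC libraries (ratio 0.998).

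The higher interferon response in GLC replicate 12 covered 13 of 21 interferon gamma response genes by more than 1 on the log2 scale, with a list median of 1.26 above the other 5 GLC libraries. After TMM scaling the median of all genes differed by 0.018, so a shift shared by all genes does not give the 1.26. TMM itself brings that median near 0, so this value is no separate test of the library's scale. More cells of another type stay open: of the lists of B, plasma, macrophage, dendritic and natural killer cells 0 of 5 lay above all other GLC libraries, but GLC replicate 78 was highest in each and hides a smaller gain. The dendritic list median was 0.502 above the other GLC libraries, over 6 measured members, and that of the cell cycle list 0.699. The dendritic list was fixed with Bst2, which the type I interferon list also holds. Its gain may thus not be separate from the interferon response. No biological explanation was tested. Without this library the difference between GLC and WT in the list mean shrank from 0.415 to 0.251 for the type I and from 0.387 to 0.164 for the interferon gamma list, and both passed the preset test (adjusted p of 0.000135 and 0.00013).

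With the preset correlation 12 lists passed, among them regulatory T cell genes, while edgeR called 0 genes (563 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 2. Chance cannot be excluded: 35 of 100 splits of the libraries gave at least 12 lists (up to 27 in the other splits), and 17 gave a camera p for regulatory T cell genes as small as the real 6.7e-08 (down to 3.82e-16). For the type I interferon list 5 of 100 splits, the real one included, gave a p as small as 1.97e-09 (down to 6.55e-12). For genes the splits decide nothing, since all 100 give at least the real 0; of the 99 others 89 called 0, 8 called 1 to 3, and 2 called 22 and 64. Those 2 may reflect a structure among the mice, which was not tested. Members of each passing list moved together from mouse to mouse, with an estimated correlation of at least 0.11 where the test presets 0.01, and 0 lists passed when it was used, so the preset test may overstate these calls.

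RNA carried over from B cells stays open for the regulatory T cell genes, although the selection kit should remove such cells. All 28 genes together gained 397 CPM more than 8 B cell genes did, but with an SE of 237 (exact permutation p = 0.134). A first version of this test, on Foxp3, Lrrc32, Nrp1 and Nt5e alone, gave 98.4 CPM (SE 35.4) and appeared to exclude B cell RNA; it was replaced because these are the members of smallest p. Cd74, the most abundant of the 8, was at 42.9 ± 13.4 CPM in WT and 58.2 ± 20.2 CPM in GLC (SD, n = 5 and n = 6), and 1 of 20 B cell genes is in another list. The B cell score as a covariate lowered the difference of the regulatory list mean from 0.302 (SE 0.21) to 0.0766 (SE 0.157), and the call ended because the difference shrank (adjusted p = 0.231, over a range of 9.76e-09 to 0.572 across alternatives). With the Gm42418 share as a covariate the preset test passed (adjusted p = 7.08e-06) and the difference of the list mean did not shrink (0.317, SE 0.261), which counts against this share as the whole cause. The part that went with the share was -0.0142 (SE 0.137) of 0.302 over all libraries. It was 0.163 (SE 0.128) of 0.364 without WT replicate 1, the library of highest share, so a single library decides this and the share stays open. An effect of the genotype, depth, which differed between the groups, and a state shared by some mice were not told apart by these tests.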

How the results depend on the processing

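Added after seeing the data were the Gm42418 share as a covariate, leaving out GLC replicates 9 and 78 together and the exact test of list means; for each change below the cause was not tested. No gene passed in either direction under any setting but DESeq2 (2 higher) and no filter (1 higher). Pggt1b stayed higher and short of the threshold under every setting, with a log2 fold change from 0.20 with surrogate variables to 0.39 without GLC replicate 11. Of the other named genes, 1374 values kept direction and side, Igkv5-48 passed under 2 settings, and with surrogate variables Il2ra (-0.0241), Birc5 (-0.0261) and Igkc (-0.0384) turned negative.

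Adjusted p of the regulatory, naive, effector and memory, type 1 and follicular lists was 0.504, 0.504, 0.504, 0.504 and 0.553 with an estimated correlation, 0.572, 0.572, 0.572, 0.572 and 0.59 with fry, and 0.513, 0.51, 0.513, 0.51 and 0.513 with exact tests of list means, so none of these calls held there. With the B cell score it was 0.231 for the regulatory, 0.0537 for the naive, 0.659 for the effector and memory and 0.932 for the follicular list; the activation list passed as lower (0.000164), and the type 2 (0.585) and type 17 (0.173) lists reversed. With the Gm42418 share the activation list reversed and passed as higher (0.00787), the type 2 list passed (0.0256) and the follicular list did not (0.0631). Without GLC replicates 9 and 78 the type 17 list reversed (0.914) and the follicular list lost its call (0.262).

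Leaving out 1 library at a time gave adjusted p from 0.0141 to 0.933 for activation, 3.78e-05 to 0.0938 for effector and memory, 0.00994 to 0.811 for type 2, 0.0651 to 0.98 for type 17, 0.000526 to 0.415 for follicular and 0.381 to 0.856 for prenylation and sterol lists, with reversals in activation, type 17 and prenylation lists. The regulatory (9.76e-09 to 0.00155), naive (3.21e-06 to 0.00768) and type 1 (4.99e-07 to 0.00334) lists passed each time. Signalling and metabolism lists past the threshold numbered 4, against 2 with the B cell score, 0 with estimated correlation, fry or exact tests, 6 with the Gm42418 share, 5 without GLC replicates 9 and 78, and 4 to 6 with 1 library left out. Glycolysis and unfolded protein response genes passed as higher with the Gm42418 share (0.000866 and 0.00116), and glycolysis genes without GLC replicates 9 and 78 (0.0219). Lists of other cell types numbered 3, against 0 with the B cell score and in those 3 tests, 2 with no filter, where the B cell list failed (0.281), 1 without GLC replicates 9 and 78, and 0 to 4 with 1 library left out. Technical lists numbered 0, and 1 with the Gm42418 share (heat shock genes, higher, 0.0256).

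No paired analysis was possible because the groups share no replicate number. Sex as a covariate was not run, since Y-linked reads occur in 1 library of 1 group and the term would equal leaving out GLC replicate 9. In simulated data of this comparison 1.25-fold changes were found for 15.2% of genes and 2-fold changes for 75.6%.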

Other observations

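Chosen only after the result was seen were the test by group, the count of neighbours without the TRIM genes and the relations between lists. Some genes had a gap in level between a low and a high set of libraries, whatever the group. Searching 12178 tested genes, leaving out antigen receptor segments, Xist and Y-linked genes, for a gap of at least 1.5 in log2 CPM between neighbouring libraries with at least 2 libraries on each side gave 21 genes on 13 chromosomes, all named after their values were seen. Rps3a3, a processed pseudogene on chromosome 13 (positions 108670603 to 108671397), was at 182 CPM or more in WT replicates 3, 4 and 5 and GLC replicates 9 and 11 and at 2.92 CPM or less in the other 6 libraries. Trim12a, a TRIM family gene on chromosome 7 (positions 104299894 to 104315466), was between 40.7 and 59.1 CPM in WT replicates 1, 2 and 5 and GLC replicate 6, at 25.9 CPM in the pooled GLC replicate 78, and at 0.708 CPM or less in the rest. Rab6b, a Golgi GTPase gene on chromosome 9 (positions 103111787 to 103185276), was between 22.8 and 39.4 CPM in WT replicates 1 and 4 and GLC replicates 6, 10 and 11, at 14.5 CPM in the pool, and at 0.991 CPM or less in the rest. Zfp990 on chromosome 4 was at 4.07 CPM or more in 6 libraries and at 0.0843 CPM or less in 5. The low side was not near 0 for every gene. In WT replicate 4 and GLC replicate 10, Ctse was at 204 CPM or more and Xkr6 at 27.7 CPM or more. In the rest Ctse was between 21.8 and 54.2 CPM and Xkr6 between 2.83 and 8.29 CPM.

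The group does not account for these genes, since 0 of the 21 split the libraries into WT and GLC and 0 had an unadjusted edgeR p under 0.05. An event that hit whole libraries was argued against by a median absolute correlation of 0.272 between such genes on different chromosomes. Alleles that differ between mice may explain them, although the mice are described as C57BL/6 and no mixed background is stated. Genes within 2 Mb followed the same split (absolute correlation of at least 0.8) in 18 of 483 pairs, against 1058 of 246670 pairs on other chromosomes. This passed a Fisher exact test (odds ratio 8.99, p = 9.63e-12), although neighbouring genes are not independent. Of the 18 pairs, 12 had Trim12a, Trim30d or Gm1966 of chromosome 7 as the first gene, where TRIM paralogs can share reads, and without these 3 genes and with no gene of the set counted as a neighbour it was 6 of 418 pairs against 951 of 211990 (odds ratio 3.23, 95% interval 1.18 to 7.12, Fisher exact p = 0.0124). Of these 6 pairs, 3 had Art2b as the first gene. Art2b also lies on chromosome 7 (positions 101576970 to 101585600) and split the libraries as Trim12a did (0.927 CPM or less against 3.52 CPM or more). Both counts thus rest partly on 1 region. Reads shared among TRIM paralogs would not give the split of Art2b. Reads shared between paralogs were not tested otherwise and stay open.

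Of the lists tested, 5 were chosen after the result was seen for comparison with the regulatory T cell list. Type 2 helper, inhibitory receptor and adhesion genes were not compared. Their means, like the regulatory mean, were highest in GLC replicate 78 and lowest in WT replicate 2. The relations below thus do not set these 5 lists apart. Across the 11 libraries the mean of the regulatory T cell list was compared with that of these 5 lists, with p adjusted over these 5 only. It rose with type 17 helper genes (Pearson r = 0.798, permutation p = 0.0024, adjusted p = 0.0068; Spearman rho = 0.773, permutation p = 0.0075, adjusted p = 0.035) and type 1 helper genes (r = 0.802, permutation p = 0.0027, adjusted p = 0.0068; rho = 0.727, permutation p = 0.014, adjusted p = 0.035). Leaving out GLC replicate 78 and WT replicate 2, the farthest from the median, r was 0.614 and 0.649, and within the 6 GLC libraries it was 0.866 and 0.555. With plasma cell markers r was 0.701 (permutation p = 0.017, adjusted p = 0.021; rho = 0.609, permutation p = 0.051, adjusted p = 0.064), 0.611 without those libraries and 0.837 within GLC. With naive and homing genes r was -0.75 (permutation p = 0.0082, adjusted p = 0.014; rho = -0.618, permutation p = 0.049, adjusted p = 0.064), and -0.423 without those libraries, so it rests partly on them, and -0.77 within GLC. With early activation genes r was 0.505 (permutation p = 0.11, adjusted p = 0.11; rho = 0.527, permutation p = 0.099, adjusted p = 0.099), 0.531 without those libraries and 0.4 within GLC, and both lists hold Il2ra.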
